A study of Saccharomyces cerevisiae with 25 samples.

How the data were processed

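RNA was taken from one culture at 25 time points, with 1 library in high phosphate and 24 without phosphate. Per the labels' protocols, cells were lysed and RNA was extracted in 96-well plates with a column kit, cDNA was made for each sample and the cDNA was sequenced on an Illumina instrument. Bowtie and the genome build R64 are named in the submitters' processing notes. The counting program, annotation, strand setting and handling of shared reads are not given in the sources used here.

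The deposited values are log2 of RPM, the reads of a gene per 1000000 reads of its library. The antilogs of each column sum to 1000000. If the lowest value listed in a library is taken as 10 reads, 95.7% of low values are whole numbers of reads. The lowest value was therefore read as 10 reads, and values below it are blank. Over all values 94.1% lay within 0.01 of a whole number of reads. Fractional reads were taken as a sign of reads divided between similar genes, which was not checked, and the partners were not traced. Genes with fractional reads in most libraries (296 of those tested) are called genes that share reads. The design text speaks of values relative to the first time point, but the deposited values are levels, with the 0 min library having its own. Depth was read back as 413033 to 4162690 reads per library. A gene at the floor of 10 reads has a counting error far larger than an abundant one.

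Of 6701 rows, 51 carried no gene name and held no value, and 932 named genes were blank in all libraries. Genes were tested if listed in at least 13 of the 25 libraries and in at least 3 of 8 in each window, which left 5298, of which 5230 had a 0 min value. Blanks were left missing and no pseudocount was needed. Names were matched to the R64 annotation for 5169 of the tested genes by symbol, locus tag or alias, and coordinates are 1-based positions of the annotated gene.

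The main test was limma 3.58.1 in R 4.3.3 with a variance trend. The model held an indicator for the 0 min library and a natural cubic spline of time with 4 degrees of freedom over the libraries without phosphate. Contrasts were the mean of the fitted values over a window against 0 min, or late against early, and a joint test of all spline terms asked for any change over time. A call needed a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 change, or for the joint test a fitted range, of at least 1. Residuals had 19 degrees of freedom, a median SD of 0.218 and a median lag-1 autocorrelation of -0.13. SE is the standard error from the fit. Levels given for a window are geometric means over its listed libraries.

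Before the data were examined, 30 gene lists, the windows, the model, the alternatives and the rule for named genes were fixed. The rule took the 10 largest rises and falls among called genes that moved one way in all 8 libraries of a window (for late against early, with no overlap of values), all PHO regulon members, and in each other list the 4 members with the largest test statistic. Time courses of OPI3, RPL3 and the IMD genes, and PHO4, PHO90, TIS11 and FRE2, were chosen after their values were seen. Lists of at least 5 genes were tested against other genes with camera, on 4334 genes listed in all libraries, with the preset correlation of 0.01, and 27 lists qualified. No theme was named outside these lists. The lists were written from general knowledge of yeast, not from these libraries.

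The procedure was tested on simulated data. All simulated genes had the same dispersion, and as many rises as falls were set. No shift in the share of ribosomal protein genes and no library standing apart was built in. The false calls below therefore leave out such sources of error. With 186 of 5280 genes stepped by 1.5 log2 units in the middle of the course, late against early calls recovered 98.4% of them with 0 false calls. With 189 of 5276 genes stepped at transfer by 1.5, early against high phosphate calls recovered 94.2% with 0 false calls. The step in the middle of the course gave 1 false call of 179 late against high phosphate and 4 of 189 for change over time, and larger steps gave up to 5 false calls in a comparison.

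Alternatives were a spline with 3 or 6 degrees of freedom, libraries centred on their median, no filter on low values beyond what the fit needs, robust empirical Bayes, array weights, window means, a minimum log2 change of 0.58, each time point left out in turn, the 15 and 30 min libraries left out together, and alternate time points. Blanks set to 5 reads, genes listed in all libraries only, precision weights from reads, and list tests with 6 degrees of freedom or with each time point left out were added after seeing the data. Tests on counts were planned only for a deposited count table and were not run on the reads recovered from the log2 values, which lack all values under 10 reads. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.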

Results

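The series followed one culture of budding yeast (Saccharomyces cerevisiae, strain background BY4741) through 6 hours without phosphate. The strain is labelled as lacking VIP1, which encodes an inositol pyrophosphate kinase, and as carrying YFP under the PHO84 promoter. One RNA-seq library was labelled 0 min, from cells in high-phosphate medium, and 24 libraries were labelled as taken every 15 min after the cells were washed and moved to medium without phosphate. Each time point had 1 library, so no value has a replicate at its own time. For the tests, the times without phosphate were divided into an early window of 15 to 120 min, a middle window of 135 to 240 min and a late window of 255 to 360 min, with 8 libraries each. The libraries held between 413033 reads at 345 min and 4162690 reads at 165 min, with a median of 1417344, as recovered from the spacing of the values. Genes were listed only where they had at least 10 reads.

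The gene named in the genotype was read first. VIP1 (chromosome XII, 937541 to 940981, R64) was listed in all 25 libraries, at 9.69 to 55.7 RPM (reads of a gene per 1000000 reads of its library) with a median of 19.8, from 10 to 105 reads. Its change over time did not pass the test, with an adjusted p = 0.147 from limma. These totals do not bear out a loss of the whole locus. The values are gene totals, and reads from any part of the locus that was left in place would be counted in them. Which part was deleted is not given in the sources used here, so the totals cannot settle the label. The libraries are described as labelled, with this left open. HIS3, LEU2 and MET17, which BY4741 lacks, were listed in 0 libraries, and URA3, which it also lacks, was listed in 8 libraries at 4.13 to 10.3 RPM.

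The early window was set against high phosphate to ask which transcripts differed on average over 15 to 120 min. IMD2, which encodes an IMP dehydrogenase of guanine nucleotide synthesis (chromosome VIII, 554396 to 555967), fell by 2.39 on the log2 scale (SE 0.20, adjusted p = 1.0e-08), and its paralog IMD3 fell by 1.36 (SE 0.25). ICY2 (chromosome XVI, 74309 to 74719) rose by 1.92 (SE 0.26), from 5.59 RPM at 0 min to a mean of 21.1 in the window. SHM2 (serine hydroxymethyltransferase) rose by 1.11 (SE 0.14), MET6 (methionine synthase) by 1.01 (SE 0.16) and ADE17, an enzyme of purine synthesis, by 1.01 (SE 0.16). These 6 genes, 4 higher and 2 lower, were all that passed of 5230 tested with limma. The test reads the mean over the window, so changes that are brief or begin near its end can be missed. The PHO regulon, for one, had a median log2 change of 1.33 in the 120 min library. An adjusted p under 0.05 alone was reached by 10 genes and an unadjusted one by 428. IMD2 and IMD3 are genes that share reads, so their separate values are uncertain. Without the 15 min library 12 genes passed (7 higher and 5 lower), and without the 120 min library 4 did (2 higher and 2 lower). With 6 degrees of freedom in the curve 12 passed, with array weights 11 did, and with plain window means in place of the curve only ICY2 did. With every second time point from 15 min, IMD3, MET6 and ADE17 did not pass. The 0 min value of ICY2 rests on 11 reads, 1 above the floor, whose counting error alone is 0.435 on the log2 scale, larger than its SE from the fit.

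None of the 18 members of the PHO regulon with a value, the targets of the transcription factor Pho4, passed the early test singly. The largest change, 0.94, was under the required size of 1. The count adjusted over the list alone was therefore 0 whatever the p-values. PHO84, the high-affinity phosphate transporter, stood at a log2 change of 0.94 (SE 0.27, adjusted p = 0.212) and SPL2, a regulator of low-affinity phosphate uptake, at 0.88 (SE 0.29). With the 15 and 30 min libraries left out, both passed. As a set the list was higher than other genes by camera, with a median log2 change of 0.42 (adjusted p = 2.8e-10), and with adjusted p = 0.146 with an estimated correlation. Chaperone genes had a median of 0.39 (adjusted p = 5.1e-11, and adjusted p = 0.112 with an estimated correlation), with HSP82 at 0.99 (SE 0.28) and HSP10 at 0.84 (SE 0.19), neither past the test. General stress genes had a median of 0.40 (adjusted p = 6.6e-07, and adjusted p = 0.477 with an estimated correlation). Ribosome biogenesis genes had a median of -0.45 (adjusted p = 1.0e-05, and adjusted p = 0.627 with an estimated correlation). Sulfur genes had a median of 0.32 (adjusted p = 1.1e-05, and adjusted p = 0.0672 with an estimated correlation). In all, 16 of 27 lists passed with the preset correlation, 11 upward and 5 downward, and 0 with estimated correlations. Adjusted over the list alone, the purine list had 3 members that fell in place of 2, the nitrogen list 1 that rose in place of 0, and the other lists kept their counts. Counts adjusted over a list, here and below, kept the required size of 1. Lists with no member of that size could not change.

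The middle window showed the PHO regulon raised. Against high phosphate 16 of its 18 measured members rose, with 16 also when adjusted over the list alone and a median log2 change of 2.76. SPL2 rose by 4.02 (SE 0.29), PHO84 by 3.42 (SE 0.27), PHO11, an acid phosphatase, by 3.24 (SE 0.25) and PHO5, the main secreted acid phosphatase, by 3.03 (SE 0.18). PPN1, an endopolyphosphatase, was at 0.59 (SE 0.18) and PHM7 at 0.73 (SE 0.66), and neither passed. In the same window 78 of 137 cytosolic ribosomal protein genes and 32 of 52 ribosome biogenesis genes fell (78 and 33 adjusted over the list alone). General stress genes rose in 25 of 35 cases (25 adjusted over the list alone), with 10 of 19 trehalose and glycogen genes (11 adjusted over the list alone) and 11 of 19 nitrogen catabolite genes (11 adjusted over the list alone). In total 564 genes passed, 331 higher and 233 lower, while the median of all genes moved by 0.17. With each library centred on its median 558 passed, 223 higher and 335 lower, among them 16 PHO regulon, 23 stress, 8 trehalose and glycogen and 6 nitrogen genes that rose and 109 ribosomal protein and 41 ribosome biogenesis genes that fell. With plain window means in place of the curve 114 genes passed, 104 higher and 10 lower of all genes, so most of the falls named here were not called. Higher calls over all genes dropped too, from 331 to 104. Lower genes also numbered 133 without the 225 min library and 144 without the 240 min library.

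The order of these changes was read from the single libraries. A gene's onset is the first of 3 consecutive time points at least 1 log2 unit from its 0 min value. PHO84 and SPL2 reached it at 90 min, VTC1, VTC3 and VTC4 of the vacuolar transporter chaperone (polyphosphate polymerase) complex at 105 min together with PHO12, PHO5, PHO89, PHO81 and PHM6 at 120 min, VTC2 at 135 min, PPN1 at 210 min and PHM7 at 225 min. The median onset of the PHO regulon was 120 min. Onsets of lists were read only over members that passed late against high phosphate and had an onset. The median was 195 min for 33 general stress genes, 195 min for 35 ribosome biogenesis genes and 210 min for 136 ribosomal protein genes. Smaller or shorter departures were read before those of the PHO genes. The first stress gene onset was at 15 min. At 45 min the median log2 change was 0.91 for stress genes and -0.76 for ribosome biogenesis genes, against 0.03 for the PHO regulon. Of 35 stress and 52 ribosome biogenesis genes 0 passed the early test. That test reads the mean over the window, and the lowest ribosome biogenesis value, -0.71, was under its required size. It therefore cannot tell these departures from scatter of single libraries, which was not excluded. At 15, 30 and 60 min the medians were 0.52, 0.64 and 0.48 for stress genes. For ribosome biogenesis genes they were -0.48, -0.74 and -0.49. PHO84 stood at 95.0 RPM at 0 min, 153 at 75 min, 598 at 120 min and 988 at 180 min, and PHO5 at 308, 308, 822 and 2808. At 180 min the median log2 change was 2.87 for the PHO regulon and -0.44 for ribosomal protein genes, and at 225 min these were 2.92 and -2.35.

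**Figure D1:**
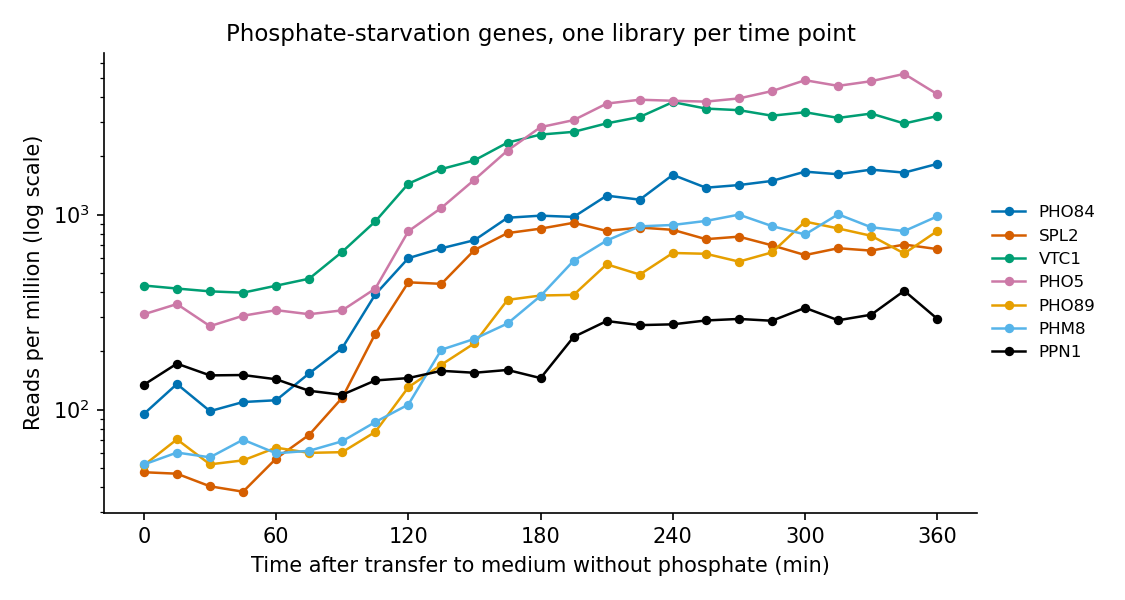
RPM (log axis) of PHO84, SPL2, VTC1, PHO5, PHO89, PHM8 and PPN1 against time in minutes, 1 point per library, with the high-phosphate library at 0 min. PHO84 and SPL2 leave their starting level first, reaching the onset level at 90 min, and PPN1 last, at 210 min.

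**Figure D2:**
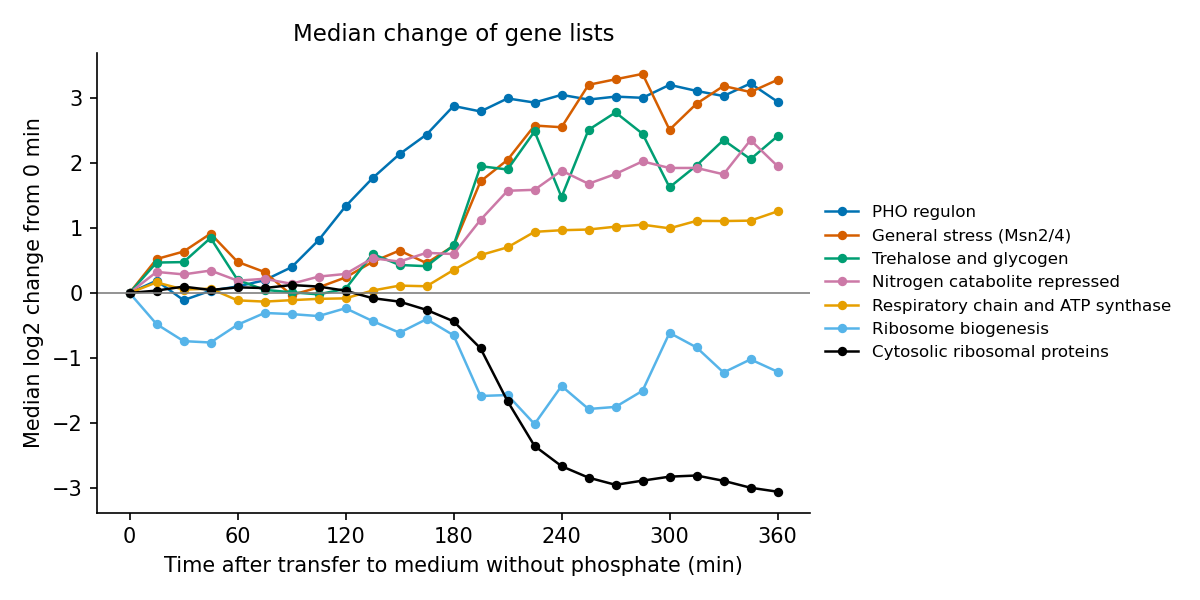
Median log2 change from the 0 min library over the measured members of 7 gene lists against time in minutes, 1 point per library. The PHO regulon median is 2.87 at 180 min, when that of ribosomal protein genes is -0.44, and the latter is -2.95 at 270 min.

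The late window was compared with high phosphate to describe the state reached after prolonged starvation. Here the median of all genes tested moved by 0.41 on the log2 scale. The values are shares of each library, and ribosomal protein genes held 33.8% of reads at 0 min and between 4.55% and 5.39% in the late libraries. Changes below are as measured, and the median of each main list relative to all genes is given beside them. All 18 measured PHO regulon members rose (18 adjusted over the list alone), with a median log2 change of 2.99, or 2.58 above the median of all genes. PHM8, a nucleotidase, rose by 4.12 (SE 0.17), PHO84 (chromosome XIII, 24037 to 25800) by 4.05 (SE 0.27, adjusted p = 5.3e-13), PHO5 (chromosome II, 429548 to 430951) by 3.83 (SE 0.18, adjusted p = 3.2e-16) and PHO89, a sodium-coupled phosphate transporter, by 3.79 (SE 0.21). PHO84 averaged 1583 RPM late and PHO5 4441. PPN1 rose least, by 1.22 (SE 0.18), and did not pass once libraries were centred on their medians (0.80), when the other 17 did. The list as a set passed camera (adjusted p = 8.5e-14, and adjusted p = 0.115 with an estimated correlation). PHO5, PHO11 and PHO12 are genes that share reads, PHO84 overlaps a noncoding RNA gene, and CTF19 was listed in 0 libraries.

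Of the regulators of the pathway and the low-affinity carriers, 4 of 13 rose (4 adjusted over the list alone). DDP1, a polyphosphate and diphosphoinositol phosphatase, rose by 2.37 (SE 0.16), PLC1, phospholipase C, by 2.12 (SE 0.17), KCS1, the other inositol pyrophosphate kinase, by 1.90 (SE 0.16) and PHO4 by 1.11 (SE 0.24). With libraries centred on their medians 3 rose and 1 fell. The set did not pass camera (adjusted p = 0.0860). PHO85, the cyclin-dependent kinase that acts on Pho4, was at 0.89 (SE 0.18), and the low-affinity transporter gene PHO90 at -0.88 (SE 0.25), both under the size required.

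Cytosolic ribosomal protein genes fell almost as a block. In the late window 136 of 137 were lower than in high phosphate (136 adjusted over the list alone), with a median log2 change of -2.96, or -3.37 relative to all genes. RPS12 fell by 2.90 (SE 0.17), RPL16B fell by 3.27 (SE 0.18) and RPS26B fell by 3.55 (SE 0.27). Many of these genes come in near-identical pairs, and RPS26B is a gene that shares reads, so single members are less certain than the list. Camera gave adjusted p = 6.4e-118, and adjusted p = 0.0539 with an estimated correlation. Ribosome biogenesis genes fell in 35 of 52 cases (35 adjusted over the list alone), among them RPA190, the largest subunit of RNA polymerase I, by 2.24 (SE 0.32) and NOP56, which fell by 1.60 (SE 0.26). After centring 47 fell. That list passed camera with adjusted p = 3.0e-16, and adjusted p = 0.236 with an estimated correlation. The share of reads from ribosomal protein genes was 37.1% at 90 min, 25.8% at 180 min, 7.88% at 225 min and 4.55% at 360 min.

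**Figure D3:**
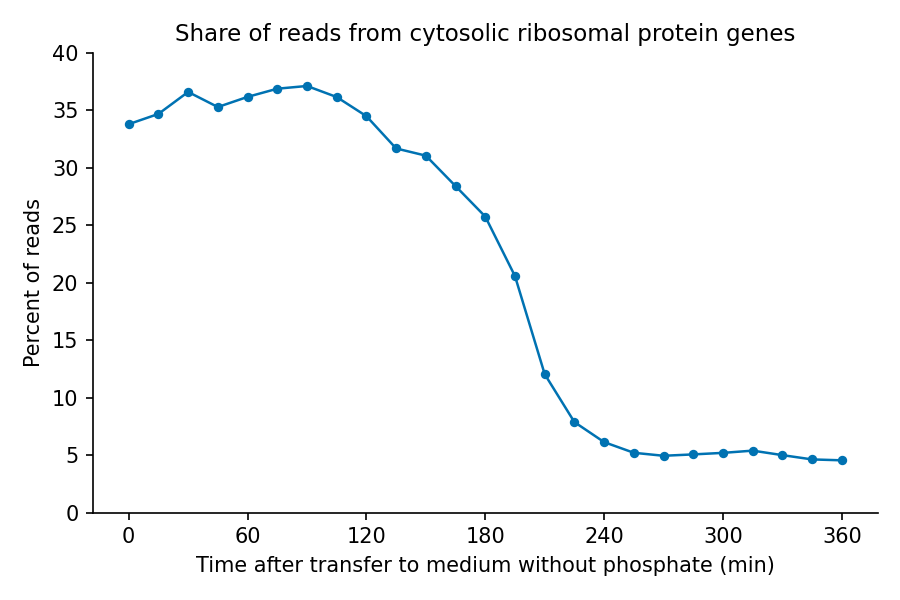
Percent of all reads that fall on cytosolic ribosomal protein genes (axis from 0) against time in minutes, 1 point per library. The share is 33.8% at 0 min, 25.8% at 180 min and 4.55% at 360 min.

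Stress and reserve carbohydrate genes rose late. General stress genes under Msn2 and Msn4 rose in 34 of 35 cases (34 adjusted over the list alone), with a median log2 change of 3.05, or 2.65 above all genes. SIP18 rose by 5.62 (SE 0.33), GRE1 by 5.06 (SE 0.27) and HSP26, a small heat shock protein, by 4.20 (SE 0.21). The set passed camera (adjusted p = 4.2e-15, and adjusted p = 0.222 with an estimated correlation). With libraries centred on their medians 32 stress genes rose. PHM8 is also a member of this list. Trehalose and glycogen genes rose in 17 of 19 cases (17 adjusted over the list alone), including GPH1, glycogen phosphorylase, by 3.17 (SE 0.34) and TPS1, trehalose phosphate synthase, by 2.35 (SE 0.29), with camera adjusted p = 2.0e-04, and adjusted p = 0.355 with an estimated correlation. The largest rise of all was that of YMR175W-A, by 5.70 (SE 0.32), an open reading frame 58 bases from SIP18, so reads of one transcript could reach both. FMP16 rose by 4.82 (SE 0.33), PAI3, a proteinase A inhibitor, by 4.76 (SE 0.29), TKL2, a transketolase, by 4.75 (SE 0.38) and GND2, a phosphogluconate dehydrogenase, by 4.63 (SE 0.40).

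Degradation and nitrogen genes rose with them. Autophagy and vacuolar protease genes rose in 19 of 22 cases (19 adjusted over the list alone), among them PRB1, vacuolar proteinase B, by 2.77 (SE 0.25) and ATG19 by 2.70 (SE 0.23), with camera adjusted p = 8.8e-06, and adjusted p = 0.210 with an estimated correlation. Genes under nitrogen catabolite repression rose in 16 of 19 cases (16 adjusted over the list alone). PUT4, a proline permease, rose by 3.96 (SE 0.34) and GAP1, the general amino acid permease, by 3.63 (SE 0.25), with camera adjusted p = 1.5e-04, and adjusted p = 0.210 with an estimated correlation. With libraries centred on their medians, 18 autophagy and 14 nitrogen genes rose.

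Energy metabolism lists had median log2 changes of 0.58 to 1.34. The stress, carbohydrate, degradation and nitrogen lists had 1.90 to 3.05, a difference that was not tested. Nuclear genes of the respiratory chain and ATP synthase rose in 22 of 35 cases (22 adjusted over the list alone), such as SDH4 by 1.97 (SE 0.20) and CYT1 by 1.72 (SE 0.20), but in 9 with 1 lower once libraries were centred on their medians. Camera gave adjusted p = 1.2e-07, and adjusted p = 0.210 with an estimated correlation. In the TCA cycle 10 of 15 rose (10 adjusted over the list alone), MDH1 by 2.07 (SE 0.18) among them, and 6 rose with 1 lower after centring. Camera gave adjusted p = 8.6e-04, and adjusted p = 0.210 with an estimated correlation. In glycolysis and fermentation 8 of 17 rose (8 adjusted over the list alone), and 3 rose after centring. The rises were led by the glyceraldehyde phosphate dehydrogenase gene TDH1 at 3.89 (SE 0.24) and the enolase gene ENO1 at 3.26 (SE 0.19). Both are genes that share reads. Camera gave adjusted p = 5.2e-06, and adjusted p = 0.236 with an estimated correlation. Among hexose carriers and glucose-repressed genes 4 of 12 rose (4 adjusted over the list alone), including ACS1 by 1.75 (SE 0.32), and 3 rose after centring. Camera did not pass for this list (adjusted p = 0.992), and it pointed downward where the median of 0.58 was above 0. It compared 7 of these 12 genes with other genes and not with 0, and the median of all genes tested was 0.41.

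Purine and one-carbon genes went both ways. Late against high phosphate 9 of 19 rose and 3 fell (9 and 3 adjusted over the list alone). ADE17 rose by 3.21 (SE 0.16), GCV2, a glycine cleavage subunit, by 2.24 (SE 0.17) and SHM2 by 1.68 (SE 0.14). IMD2 fell by 4.44 (SE 0.20), from 1585 RPM at 0 min to a mean of 72.8 late, and IMD3 and IMD4 were the others that fell. IMD2 had passed its onset level by 30 min, before the PHO genes. The set passed camera upward (adjusted p = 0.0355, and adjusted p = 0.278 with an estimated correlation).

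**Figure D4:**
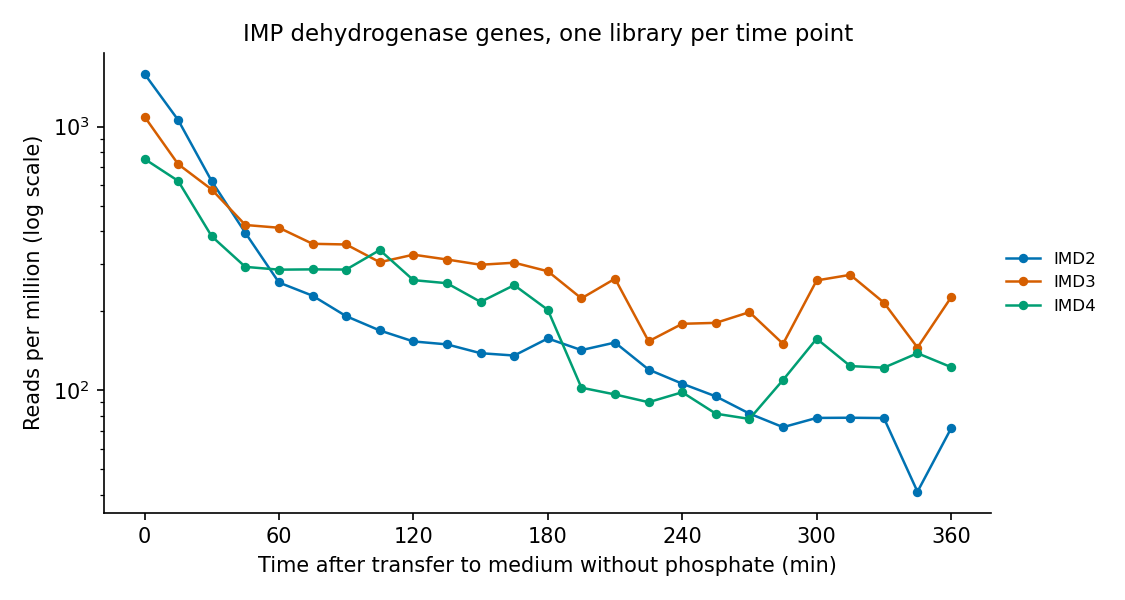
RPM (log axis) of IMD2, IMD3 and IMD4, each a gene that shares reads, against time in minutes, 1 point per library. IMD2 starts at 1585 and stands at 228 by 75 min and 72 at 360 min.

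Further metabolic and stress lists were read in the same window. Adjusted over the list alone, each count in this paragraph was the same. Amino acid genes under Gcn4 rose in 11 of 41 cases, led by HIS4 at 2.50 (SE 0.16), and after centring 3 rose and 2 fell. Sulfur genes rose in 8 of 21 cases and fell in 2, with MET16 at 1.67 (SE 0.22) and SAM1 at -1.12 (SE 0.15), and after centring 1 rose and 4 fell. Zinc genes rose in 4 of 13 cases, including ZAP1 by 1.46 (SE 0.29), and after centring 3 rose and 1 fell. In the iron regulon 3 of 20 rose and 1 fell, the ferric reductase gene FRE1 by 2.64 (SE 0.38). After centring, 0 iron genes rose and 4 fell. Camera, which did not pass (adjusted p = 0.714), pointed downward beside a median of 0.39. It compared 11 of the 20 with other genes, and the median of all genes tested was 0.41. In the phospholipid list 1 of 19 fell, the inositol transporter gene ITR1 by 1.21 (SE 0.18), and 5 fell after centring. That list passed camera downward (adjusted p = 0.00768, and adjusted p = 0.236 with an estimated correlation). Chaperone genes rose in 5 of 16 cases, including SSA1 by 2.42 (SE 0.25), cell wall genes in 3 of 15 with 1 lower, and unfolded protein response genes in 1 of 12, ERV2. After centring these were 3 chaperone genes with 1 lower, 3 cell wall genes with 2 lower and 0 unfolded protein response genes.

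Cell cycle lists were read for arrest, and the proteasome list was read beside them as a separate list. Of 23 G1/S genes 0 passed, of 9 histone genes 0 passed and of 32 proteasome genes 0 passed by limma. The same counts held when adjusted over the list alone. The largest changes were -0.99, 0.95 and 0.79, all under the required size of 1. These counts were thus set by size and do not show that smaller changes were absent. After centring 5 G1/S and 3 histone genes were lower. CDC45, a replication factor, stood at -0.99 (SE 0.32), and passed with centring, at -1.41. Of 17 G2/M genes 3 rose (3 adjusted over the list alone), including CLB1 by 1.03 (SE 0.23), and 0 after centring. Of 14 M/G1 genes 5 rose (5 adjusted over the list alone), including the daughter-cell genes DSE4 by 1.60 (SE 0.18) and DSE1 by 1.41 (SE 0.22) and the chitinase gene CTS1 by 1.04 (SE 0.14), and 1 after centring. M/G1 genes passed camera (adjusted p = 0.0164, and adjusted p = 0.233 with an estimated correlation).

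Lists of mating type and meiosis genes gave few calls. Of 7 genes of MATa haploid cells 1 rose late, MFA1 by 1.44 (SE 0.18), and of 6 measured genes of alpha cells, diploids and sporulation 1 rose, the meiotic regulator NDT80 by 1.93 (SE 0.30), the same counts as adjusted over the list alone. Transcripts of the mitochondrial genome had 0 members tested. Late against high phosphate 1460 genes passed in all, 1102 higher and 358 lower. With each library centred on its median 1182 passed, 566 higher and 616 lower, so the balance of directions rests on the scaling. The comparison rests on the single 0 min library, which was assumed to vary like the others.

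The late and early windows were also compared with each other, which does not use the 0 min library. PHO regulon genes rose in 19 of 19 cases (19 adjusted over the list alone), with a median log2 change of 2.73, or 2.24 above all genes. PHM8 rose by 3.69 (SE 0.07), PHO5 by 3.57 (SE 0.08), PHM6 by 3.41 (SE 0.06) and GIT1, a glycerophosphoinositol transporter with no value at 0 min, by 3.34 (SE 0.18). Camera gave adjusted p = 4.1e-08, and adjusted p = 0.253 with an estimated correlation. PHO86 and PPN1 did not pass after centring (0.67 and 0.65). Ribosomal protein genes fell in 136 of 137 cases (136 adjusted over the list alone), RPL9A by 3.80 (SE 0.09) the most. Theirs was the 1 list that also passed with an estimated correlation, at adjusted p = 0.0454, against 11 of 27 lists, 9 upward and 2 downward, with the preset one.

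Stress genes rose late against early in 34 of 36 cases (34 adjusted over the list alone), GRE1 by 5.11 (SE 0.12), and ribosome biogenesis genes fell in 22 of 52 (22 adjusted over the list alone), 41 after centring. HXT5, a hexose transporter gene with no value at 0 min, rose by 4.60 (SE 0.21). HPF1, a cell wall mannoprotein gene that shares reads, rose by 4.32 (SE 0.07). In the PHO signalling list 6 of 13 rose (6 adjusted over the list alone), KCS1 by 2.07 (SE 0.07) among them, and 3 rose with 1 lower after centring. In the iron regulon 3 of 20 fell and 2 rose (3 and 2 adjusted over the list alone), with a median log2 change of 0.52. Camera, on 11 of the 20 against other genes, did not pass (adjusted p = 0.265) and pointed downward. FRE1, SIT1 and FET3 fell by 1.69 (SE 0.18), 1.07 (SE 0.11) and 1.15 (SE 0.08), TIS11 and FRE2 were those that rose, and after centring 4 fell and 0 rose. In total 1372 of 5298 genes passed, 1125 higher and 247 lower, at a median change of all genes of 0.49. With centring 932 passed, 453 higher and 479 lower.

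Change at any time without phosphate was tested jointly. PHO84, SIP18 and RPL3 were among genes whose fitted levels moved with time, and 2223 of 5298 genes passed with a fitted range of at least 1 log2 unit, of 4302 past the adjusted p. OPI3, a phospholipid methyltransferase gene outside the window calls, had a fitted range of 2.46 (adjusted p = 5.7e-12). It stood at 405 RPM at 0 min, 870 at 30 min, 175 at 90 min and 793 at 225 min. Because the single libraries belong to one culture, the p-values throughout measure their scatter around a smooth curve and not the spread between cultures.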

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

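The tests of reads and ribosomal share, of blank genes and of GC content at 345 min were chosen after the pattern was seen. The windows of 8 libraries were examined for single libraries far from the rest on 5 measures, 15 groups in all, of which chance alone flags about 1 in 20. Time trends within a window also widen its range.

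The 345 min library stood apart. It listed 4553 genes, against 5256 in the next lowest of the late window, and it held 413033 reads, the fewest. VIP1 was at 5.80 on the log2 scale there, from 23 reads, against 4.29 (19.6 RPM) in the next highest late library. The floor of 10 reads was 24.2 RPM at 345 min. Any listed VIP1 value there would thus have been the highest of the window. The departure of the 345 min library from the mean of the 330 and 360 min libraries had an SD of 0.449 log2 units over 4334 genes. The SD was at most 0.314 in the other libraries with neighbours on both sides. FDH1 stood 2.03 above and PMP1 1.70 below the neighbouring libraries (-1.70).

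Low depth does not account for all of this. With the counting variance taken off, the SD was still 1.52 times the highest of the other libraries. After smooth trends on GC content and gene length were taken off every library, the SD was 0.440, against 0.449 before. It was then 1.42 times the highest other, so these trends accounted for little of the departure. Amplified copies of fewer molecules would make the departure grow more steeply with counting variance than elsewhere, and the slope was 0.795 times the highest other. No biological explanation was tested, since the design gives this library no group of its own, and a mixed or wrongly handled sample remains open. Without it 7, 550, 1460 and 1358 genes passed in the early, middle, late and late against early comparisons, and 2185 over time.

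The 165 min library held 4162700 reads, rounded, against 2009300 in the next highest of the middle window.

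Levels differed between the late and the early window for 1372 genes, by the test of that difference itself. Time in culture differs between these windows along with time without phosphate. When the times of the 24 libraries were put in 99 other orders, the highest count was 413, and 1 of 100 orders, the real one, gave as many. For change over time the real count was 2223, the highest other 1576, and again 1 of 100 orders gave as many. Most of the 99 other orders gave 0 calls in both tests. The real order therefore shows only that levels moved smoothly with time, whatever the cause.

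The median gene was higher late than early, by 0.51 on the log2 scale among genes other than ribosomal protein genes. With RPM (reads per 1000000) taken over those other genes alone, the median became -0.070. The smaller share of reads from ribosomal protein genes is thus a candidate explanation for the shift. Calls with that scaling were 387 higher and 551 lower over all genes tested, ribosomal protein genes included. Genes blank in early libraries do not account for it, since over genes listed in all libraries the median was 0.46. Without an added RNA standard, changes in RNA per cell remain open.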

How the results depend on the processing

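The blank, complete-gene, precision-weight and per-time-point list settings were chosen after seeing the data. Counts late against high phosphate stayed within 1.5 times 1460, late against early within 1.5 times 1372, and over time within 1.5 times 2223 under all settings run except the lower minimum change, which admits smaller changes. With it 10, 1151, 2414 and 2746 genes passed in the early, middle, late and late against early comparisons, and 3768 over time. The early count of 6 became 12 with 6 degrees of freedom, 11 with array weights, 12 without the 15 and 30 min libraries, and 1 with window means. The middle count of 564 became 114 with window means. Window means leave the trend within a window in the residual, which widens the error. Leaving out 1 time point gave 4 genes (without 120 min) to 12 (without 15 min) in the early window. For the other early alternatives the cause was not tested. With an estimated correlation 0 lists passed early, 0 late and 1 late against early.

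Of the values of named genes under alternatives, 5811 kept their call or its absence, 65 lost it, 75 gained it and 0 reversed. Many of these genes were named for large changes or test statistics in these libraries, so their stability is no measure for other genes. Most of the lost calls came with median centring (40), which takes the general late shift off. Most of the gained calls came with the lower minimum change (47), which can only add calls. Window means were not run for change over time. Pseudocount alternatives were not run because the values are already log2, and count-based tests, planned only for a deposited count table, were not run on the recovered reads. Depth limits weak genes most, and the 345 min library with 413033 reads has the highest floor.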

Other observations

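Of 68 genes tested that had no value at 0 min, 45 were higher late than early and 0 lower. These genes were under the floor of 10 reads at 0 min and listed often enough later, a selection that favours rises, so the split is no evidence of direction. YGR066C and YMR118C were listed in all 8 late libraries, at 26.6 to 63.3 and 29.4 to 60.0 RPM, and in none of the 9 libraries up to 120 min. FYV1, YGL102C, BUD28, FRM2 and YPL250W-A were listed in all 8 early libraries and in 0 late ones. These 7 were picked after their values were seen, and are set by the floor of 10 reads. PHO3, an acid phosphatase gene next to PHO5, fell late against high phosphate by 2.05 (SE 0.30), opposite to its neighbour, with onset at 180 min.

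Some single genes had early values that later libraries did not keep, and those named here were picked after their values were seen. HSP12, a small heat shock protein gene, went from 2422 RPM at 0 min to 6935 at 45 min and 2102 at 105 min, HXT7 from 121 to 313 and 46, and OLE1, the fatty acid desaturase gene, from 360 to 82 and 206. The hypothesis that general stress genes were higher at 30 to 60 min than at 75 to 180 min was tested after this was seen, with list medians of median-centred libraries. The difference was 0.24 on the log2 scale, 3 libraries against 8, with a two-sided exact permutation p = 0.133 over 165 splits, so scatter of single libraries could account for it. Of 35 stress genes 30 were higher at 30 to 60 min. The later span took in part of the second rise of this list, whose median change from 0 min, without centring, was -0.03 at 90 min and 0.72 at 180 min. Over single stress genes the median difference was 0.36. It was 0.35, or 96.5% of that, after trends on GC content and length were taken off, which argues against these trends as its source. Over 27 lists tested alike, hexose transport genes (1.26) and iron genes (0.57) both had exact p = 0.00606, the smallest that 165 splits can give, with adjusted p = 0.0818. So few splits over this many lists leave little room to pass the threshold, so the absence of passing lists says little. Transfer, washing and time in culture were not separated from phosphate loss. No mock transfer was analysed here, and the only high-phosphate library was that of 0 min.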
